A study of Arabidopsis thaliana with 12 samples.

How the data were processed

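Roots of 3 Arabidopsis lines with estrogen-inducible Dof1.1, Dof2.2 or PEAR2 were profiled on 12 one-colour arrays, labelled with biotin by the GeneChip WT terminal labelling kit. Mock and estriol groups of each line had 2 biological replicates, per the sample titles, and groups, doses and times follow the labels. The series text writes the third construct without its number and the titles write PEAR2, which is used here. The deposited values are log2 signals. Their making is credited to RMA in the submitters' processing notes, with no version, and the software and level of summarisation are not given in the sources used here. Values were deposited with 2 decimals, and array maxima lay between 13.81 and 14.17. Array quantiles lay closer together within each line than between lines, so the lines looked normalized separately. Levels are compared between lines only beside values after a common normalization.

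The table had 28583 entries. The list of probe identifiers and genes used here covered 17481, of which 16722 name 1 gene and 759 several. Entrez identifiers matched 16574 of the 16722 to the TAIR10.1 annotation and names matched a further 140, leaving 8 under the name they came with. Where 148 genes had several entries, the one with the highest mean over all arrays was taken, which left 16548 genes for testing. Of these, 14743 are known by locus only. The 11861 entries without exactly 1 gene name were tested in an alternative and are not named. Many well studied genes fall among these, so the tested genes are not an even sample of the genome, and the Dof1.1 transcript is not followed.

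Tests used limma 3.58.1 in R 4.3.3. One model of 6 group means over the 12 arrays was fitted, with empirical Bayes moderation (6 residual degrees of freedom, 3.94 prior degrees of freedom, prior SD 0.19 on the log2 scale). Contrasts were estriol minus mock in each line, the mean of these, each difference between a pair of them, and each difference between mock groups. P-values are two-sided, come from biological replicates and were adjusted by Benjamini and Hochberg's method over all genes of a contrast, with a threshold of 0.05. Adjusted p-values given in brackets without a name are of this kind. A gene counted as shared when past the threshold with one sign in all 3 lines, beside the count expected of independent lists. Correlations of changes across genes carry no p, since genes are not independent replicates.

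Gene lists written before the data were examined, together with the contrasts, the alternatives and the rule for naming genes, covered the Dof family, CLE peptides, CLE receptors and protophloem signalling, sieve elements, companion cells, procambium, xylem, cytokinin, auxin, cell division, glucosinolates, jasmonate, xenobiotic response, heat shock, hypoxia, nitrate, endodermis, root hairs, root cap and photosynthesis. The 6 lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, which compares a list with other genes, adjusted over the 18 tests of lists and lines. Beside it stand camera with an estimated correlation and fry, which tests whether a list's genes move one way and does not compare them with other genes.

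Genes were named by this rule. The transgenes came first. Per induction, the 10 largest rises and 10 largest falls past the threshold with both estriol arrays beyond both mock arrays were eligible. So were all members of the Dof, CLE, CLE receptor and sieve element lists past the threshold in at least 1 line, and up to 4 of each other list per line by smallest p. The 5 highest and 5 lowest of each difference between lines and each mock comparison, and the 10 shared genes with the largest mean absolute change, completed it.

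Samples with the same replicate number were checked for pairing. Deviations from the group mean correlated between mock and estriol at 0.32 in the Dof1.1 line, 0.17 in the Dof2.2 line and 0.13 in the PEAR2 line. Between lines they correlated at -0.08 to 0.11, so the value in the PEAR2 line was little higher. The numbers may pair samples within a line, and the main model does not use such pairs. Values with these pairs as a block, called paired arrays, are given where they change a call. Alternatives were quantile normalization over all arrays, centring on the 75th percentile, leaving out the 0.25 of genes with the lowest mean signal (limit 3.24), trended robust moderation, array weights, only the arrays of the lines compared, blocks by pair or by replicate number, all entries, a 2-fold minimum, and leaving out each array in turn. Tested on simulated data, in which 50 genes per size were changed among 16548, the model recovered 6%, 6% and 8% of 1.5-fold changes in the Dof1.1, Dof2.2 and PEAR2 inductions. It recovered 62%, 60% and 58% of 2-fold changes and 98%, 100% and 98% of 4-fold changes, with 7, 10 and 9 false calls. These simulated inductions had 140, 143 and 141 calls, where the real ones had 5623, 4704 and 3105. Adjustment is stricter where fewer genes change, so these shares do not give the recovery in the real inductions. Differences between lines, tested with genes changed in the Dof1.1, Dof2.2 or PEAR2 line, were recovered less often, at 4%, 0% and 0% for 1.5-fold, 26%, 10% and 10% for 2-fold and 96%, 86% and 94% for 4-fold differences. The number of arrays limits the precision, and the median SE of an induction was 0.2 and of a difference between lines 0.28 on the log2 scale.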

Results

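Transcript levels were measured in entire roots of 3 Arabidopsis lines, each with a Dof transcription factor gene under ER8, a vector whose expression is switched on by an estrogen. One line carried Dof1.1 in the background given as S32/Col, and the others carried Dof2.2 and PEAR2, both in the SUC2p::GFP-GUS background. Plants aged 68 h spent 16 h on mock plates or on plates with 10 µM estriol, an estrogen. Each of the 6 groups had 2 biological replicates, per the sample titles, which gave 12 one-colour arrays. The series concerns Dof genes with preferential expression in the phloem, the sugar-conducting tissue, and the comparisons ask which root transcripts change when such a gene is induced. Levels are log2 signals, and 16548 genes were tested. Across all entries of the table, arrays of one group correlated at 0.988 to 0.995, and mock with estriol arrays of one line at 0.91 to 0.959. Array medians lay at 5.94 to 6.16 in the Dof1.1 line, 5.41 to 5.58 in the Dof2.2 line and 6.48 to 6.57 in the PEAR2 line. The number of arrays limits the precision. No background signal was given, so group means below the lower quartile of the table's entries (3.56, 2.99 and 4.04 in mock and 3.58, 2.94 and 4 in estriol arrays of the Dof1.1, Dof2.2 and PEAR2 lines) are called dim. A dim level is not shown to lie above background, so changes from or to it are not exact, and neither is their rank. Changes are given as log2 values with the model's SE, from 2 arrays per group. No line without a Dof transgene was analysed here, so each change holds the effect of the transgene together with any effect of estriol.

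The induced transcripts come first. DOF2.2 (AT2G28810) rose in its own line from 5.65 ± 0.37 to 8.68 ± 0.46 (SD, n = 2), a log2 change of 3.04 ± 0.27 (8.2-fold, adjusted p = 1.81e-05). PEAR2 (AT5G02460) rose in its own line from 7.86 ± 0.08 to 12.25 ± 0.01 (SD, n = 2), a change of 4.38 ± 0.2 (20.8-fold, adjusted p = 8.68e-07). DOF2.2 also rose by 2.99 ± 0.27 in the Dof1.1 line (7.92-fold, adjusted p = 1.67e-05) and by 2.04 ± 0.27 in the PEAR2 line (4.11-fold, adjusted p = 0.000486). PEAR2 rose by 1.03 ± 0.2 in the Dof1.1 line (adjusted p = 0.00293) and had a change of 0.13 ± 0.2 in the Dof2.2 line (adjusted p = 0.698). In single arrays, DOF2.2 went from 5.81 and 6.28 to 9.09 and 8.97 in the Dof1.1 line, from 5.39 and 5.91 to 8.36 and 9.01 in the Dof2.2 line, and from 6.47 and 6.95 to 8.85 and 8.65 in the PEAR2 line. PEAR2 stood at 6.5 and 5.88 in mock and 7.2 and 7.23 in estriol arrays of the Dof1.1 line. Its levels were 5.71 and 6.08, then 6.03 and 6.02, in the Dof2.2 line, and 7.92 and 7.81, then 12.25 and 12.24, in the PEAR2 line. The rise of DOF2.2 differed between the Dof1.1 and Dof2.2 lines by -0.05 ± 0.39 (adjusted p = 0.992). Against the PEAR2 line it differed by 0.95 ± 0.39 in the Dof1.1 line (adjusted p = 0.269) and 1 ± 0.39 in the Dof2.2 line (adjusted p = 0.339). No difference in this rise between lines passed the threshold. The Dof1.1 transcript itself was not analysed here, because no entry names it alone.

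**Figure D1:**
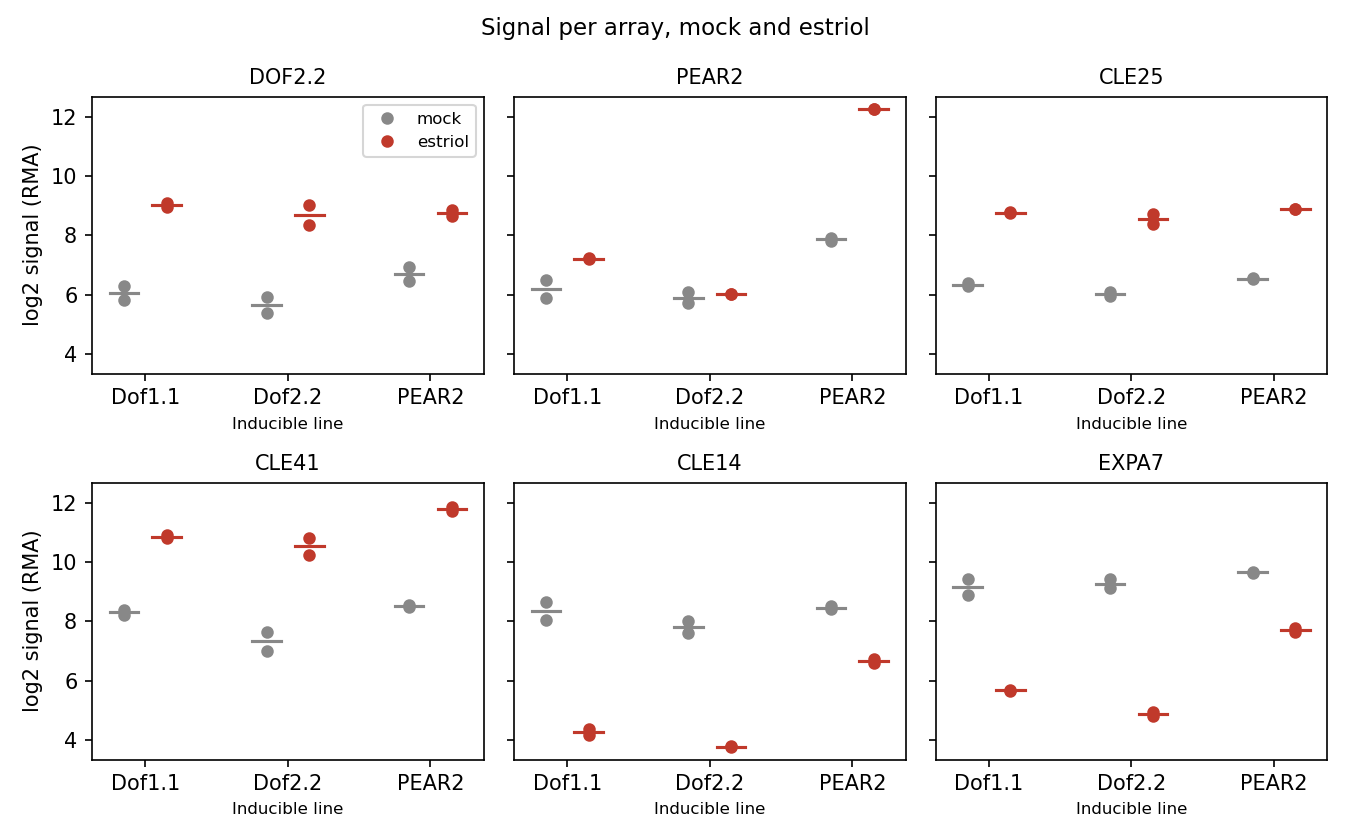
Log2 signal (vertical axis) of 6 genes in each mock and estriol array of the 3 lines (horizontal axis), with points for arrays and bars for group means. PEAR2 reached 12.25 and 12.24 with estriol in its own line, and DOF2.2 stood higher in both estriol arrays than in both mock arrays of each line.

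The Dof1.1 induction asks which root transcripts change when Dof1.1 is switched on. Transcripts for small cysteine-rich peptides of the defensin-like LCR family were among the largest rises, with LCR29 at 8.48 ± 0.49 (adjusted p = 8.36e-07), LCR42 at 8.26 ± 0.35 and LCR16 at 7.57 ± 0.16. The germin-like gene AT5G38930 rose by 8.17 ± 0.29 (adjusted p = 9.97e-08), from 3.42 ± 0.02 to 11.59 ± 0.33 (SD, n = 2). Among the falls were the peroxidase AT2G18980 at -5.86 ± 0.25 (adjusted p = 1.6e-07), the leucine-rich repeat receptor kinases AT1G51850 at -5.43 ± 0.21 and AT1G51840 at -5.3 ± 0.28, and the glycosyl hydrolase GH9C1 at -5.16 ± 0.19. AT1G18130 had a rise of 8.99 ± 0.28 (adjusted p = 4.96e-08), AT1G47317 of 8.86 ± 0.43 (465-fold) and AT4G12950 of 8.77 ± 0.27 (438-fold). Further large rises were those of AT3G42830 (8.56 ± 0.42), AT3G56520 (8.48 ± 0.34) and AT1G28630 (8.25 ± 0.18). AT5G36130 fell by 7.24 (SE 0.65) and AT1G05660 changed by -5.9 ± 0.42. Of these risers, only AT1G47317 and AT4G12950 were not dim in mock roots, where the others stood at 1.92 (LCR16) to 3.42 (AT5G38930), and AT1G51850 was dim with estriol, at 1.94. In all, 2940 genes rose and 2683 fell, 34% of those tested, of which 1152 rose and 1904 fell at least 2-fold. Both estriol arrays lay beyond both mock arrays in 63.2% of genes, where chance gives 33.3%.

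The Dof2.2 induction puts the same question for Dof2.2. LCR29 rose by 6.7 ± 0.49 (adjusted p = 4.31e-06) and the germin-like gene AT5G39120 by 5.95 ± 0.5 (adjusted p = 1.08e-05). The peroxidase AT3G01190 fell from 10.93 to 4.14 ± 0.14 (SD, n = 2), a change of -6.79 ± 0.16 (adjusted p = 2.78e-08). The UDP-glycosyltransferase AT3G46700 fell by 6.19 (SE 0.28, adjusted p = 2.76e-07) and the receptor kinase AT1G51830 by 6.04 (SE 0.21, adjusted p = 8.63e-08). Further large rises were those of AT1G47317 at 8.71 ± 0.43 (419-fold, adjusted p = 4.15e-07), AT5G59110 at 7.39 ± 0.5 and AT1G28630 at 6.83 ± 0.18. AT1G05660 changed by -7.02 ± 0.42 (adjusted p = 1.14e-06), to 3.12. Dim in mock roots were LCR29 (2.64), AT5G59110 (2.15) and AT1G28630 (2.2), while AT5G39120 stood at 3.11, and dim with estriol were AT3G46700 (2.84) and AT1G51830 (2.81). Altogether 2452 genes rose and 2252 fell, 28.4% of those tested, and 929 rose and 1596 fell at least 2-fold. Arrays of the treatments did not overlap in 61.3% of genes, against 33.3% by chance. Fitted on the 4 arrays of this line alone, the count dropped from 4704 to 3095.

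The PEAR2 induction puts it for PEAR2. AT1G28630 rose by 8.81 ± 0.18 (adjusted p = 6.01e-09), from 2.64 ± 0.16 to 11.46 ± 0.04 (SD, n = 2). LCR42 rose by 8.21 ± 0.35 (adjusted p = 5.94e-07), LCR29 by 8.01 ± 0.49 (adjusted p = 3.63e-06), LCR39 by 6.32 ± 0.35 and the pectin methylesterase AT2G47280 by 6.39 ± 0.38 (adjusted p = 3.08e-06). SWEET11, a sucrose exporter of phloem loading, rose by 4.01 ± 0.55 (16.1-fold, adjusted p = 0.000583). Among the falls were the lipid-transfer-type gene AT5G46890 at -6.84 ± 0.5 (adjusted p = 1.07e-05), the fatty acid desaturase AT1G06120 at -5.97 ± 0.31 (adjusted p = 1.68e-06), AT4G22460 at -5.5 ± 0.24 and the peroxidase AT2G39040 at -4.53 ± 0.28 (adjusted p = 3.86e-06). Dim in mock roots were AT1G28630, LCR42 (2.19), LCR29 (3.85) and AT2G47280 (3.45), and dim with estriol were AT5G46890 (2.55) and AT1G06120 (3.28). A total of 1378 genes rose and 1727 fell, 18.8% of those tested, and 647 rose and 1131 fell at least 2-fold. With array weights 2120 rose and 2349 fell, a total of 4469 against 4250 in the Dof2.2 induction. Fitted on the 4 arrays of each line alone, the totals were 3471 here and 3095 in the Dof2.2 line. The order of these lines by count thus turned with the setting. Treatments did not overlap in 61.8% of genes, against 33.3% by chance. The count of 3105 fell to 1923 without mock array 1 of this line, 1859 without mock array 2, 1915 without estriol array 1 and 2043 without estriol array 2.

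Members of the Dof family other than the transgenes changed in each line. DOF1.3 rose by 4.1, 3.41 and 5.23 (SE 0.24) in the Dof1.1, Dof2.2 and PEAR2 lines, with adjusted p = 9.83e-07, 3.67e-06 and 8.68e-07. The cycling Dof factor CDF4 rose by 3.98, 3.96 and 3.95 (SE 0.21; adjusted p = 4.9e-07, 5.9e-07 and 1.83e-06), DOF1.5 by 3.46, 3.17 and 3.43 (SE 0.2) and CDF5 by 1.48, 1.3 and 3 (SE 0.26; adjusted p = 0.00131, 0.00343 and 2.72e-05). DOF2.1 changed by -1.14, -1.33 and -0.72 (SE 0.18; adjusted p = 0.00073, 0.000309 and 0.0188). DOF1.2 fell in the Dof1.1 and Dof2.2 lines, at -1.36 and -1.3 (SE 0.3; adjusted p = 0.00522 and 0.00787), and stood at -0.04 in the PEAR2 line (adjusted p = 0.964). DOF4.6 fell in the Dof1.1 line at -0.65 ± 0.2 (adjusted p = 0.0299), against -0.5 in the Dof2.2 line (0.0918) and -0.4 in the PEAR2 line (0.226). DOF1.6 fell in the Dof2.2 line at -0.95 ± 0.22 (adjusted p = 0.00964), against -0.42 (0.19, or 0.0276 without Dof1.1 estriol array 2) and -0.55 (0.129, or 0.0427 with array weights and 0.0454 on the PEAR2 arrays alone). Dim levels were those of DOF1.3 and CDF5 in mock roots of the Dof1.1 and PEAR2 lines, DOF1.2 with estriol in the Dof1.1 line and DOF1.6 with estriol in every line and in mock roots of the Dof1.1 line. Counts and tests of the list include the transgenes DOF2.2 and PEAR2. Of 13 measured members of 35, the Dof1.1 line had 6 that rose, 3 that fell and 4 that did not pass, or 7 and 3 adjusted over the list alone. Its list test gave adjusted p = 0.328, and adjusted p = 0.674 with an estimated correlation. The Dof2.2 line had 5, 3 and 5, or 5 and 4 adjusted over the list alone, with adjusted p = 0.563 upward, and adjusted p = 0.747 with an estimated correlation, while the list's median was -0.08 and its mean 0.81. The PEAR2 line had 6, 1 and 6, or 6 and 1 adjusted over the list alone. There the test gave adjusted p = 0.0177 upward (median 0.02, mean 1.54), and adjusted p = 0.514 with an estimated correlation. With same-numbered arrays of a line as pairs it gave adjusted p = 0.125 and DOF4.6 in the Dof2.2 line 0.0266, and on the 4 arrays of the PEAR2 line alone the list gave 0.145. Without DOF2.2 and PEAR2, an alternative chosen after seeing the data, 11 members gave adjusted p = 0.719, 0.808 and 0.227 in the Dof1.1, Dof2.2 and PEAR2 lines (medians of -0.42, -0.1 and -0.04, means of 0.82, 0.66 and 1.23). The call in the PEAR2 line was lost without DOF2.2 and PEAR2 together, and removing either alone was not tested. With an estimated correlation the adjusted p-values became 0.819, 0.824 and 0.721. DOF4.6 missed the threshold in the Dof1.1 line without estriol array 2 (adjusted p = 0.176), mock array 1 (0.141) or mock array 2 (0.055), with array weights (0.0537) and on that line's arrays alone (0.0564). Missing it likewise were DOF1.2 without Dof2.2 estriol array 2 (0.0552) or mock array 2 (0.0555), DOF1.6 without Dof2.2 estriol array 1 (0.0692), and DOF2.1 in the PEAR2 line without any of its 4 arrays (up to 0.112).

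CLE peptide genes went both ways. CLE41 and CLE44 encode the peptide TDIF, which signals to the cambium. CLE41 rose by 2.56, 3.2 and 3.26 (SE 0.23) in the Dof1.1, Dof2.2 and PEAR2 lines, with adjusted p = 1.61e-05, 4.29e-06 and 9.15e-06. CLE44 rose by 0.69, 1.9 and 2.29 (SE 0.19; adjusted p = 0.0194, 4.21e-05 and 2.5e-05), CLE25 by 2.42, 2.54 and 2.35 (SE 0.15; adjusted p = 1.25e-06, 1.02e-06 and 4.33e-06) and CLE42 by 2.84, 1.88 and 2.02 (SE 0.27; adjusted p = 2.05e-05, 0.000436 and 0.000461). CLE14 changed by -4.07, -4.02 and -1.8 (SE 0.21; adjusted p = 4.9e-07, 6.08e-07 and 0.000218). CLE16 fell in the Dof1.1 and Dof2.2 lines at -1.5 and -1.46 (SE 0.25; adjusted p = 0.000992 and 0.00144), with -0.59 in the PEAR2 line (0.144, or 0.03 with paired arrays and 0.0459 with array weights). Past the threshold in the Dof2.2 line alone were CLE20 at 1.06 ± 0.2 (adjusted p = 0.00241) and CLE26 at 1.25 ± 0.28 (adjusted p = 0.00783). CLE20 stood at -0.5 (0.0801, or 0.045 with paired arrays) and -0.02 (0.961) in the Dof1.1 and PEAR2 lines, and CLE26 at 0.66 (0.0994, or 0.0414 after quantile normalization) and 0.53 (0.251). CLE1 fell in the PEAR2 line at -0.89 ± 0.27 (adjusted p = 0.0423), against -0.7 (0.0682) and -0.68 (0.0826) in the Dof1.1 and Dof2.2 lines, which paired arrays put at 0.0298 and 0.0363. The former also passed with the block by replicate number (0.0458) and without Dof1.1 estriol array 2 (0.00754), and the latter without either Dof1.1 estriol array (0.0283). Of 18 measured members of 32, 4 rose, 2 fell and 12 did not pass in the Dof1.1 line, 6, 2 and 10 in the Dof2.2 line, and 4, 2 and 12 in the PEAR2 line. Adjusted over the list alone, 4 rose and 2 fell, 6 and 2, and 4 and 2. The list test gave adjusted p = 0.837, 0.412 and 0.328, and adjusted p = 0.928, 0.747 and 0.747 with an estimated correlation. Call losses without single arrays concerned CLE44 in the Dof1.1 line (estriol array 1, 0.0603; estriol array 2, 0.0864; mock array 1, 0.107), CLE26 (Dof2.2 estriol array 2, 0.0577) and CLE1, which missed without any of 8 arrays (up to 0.191) and after quantile normalization (0.0594).

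**Figure D2:**
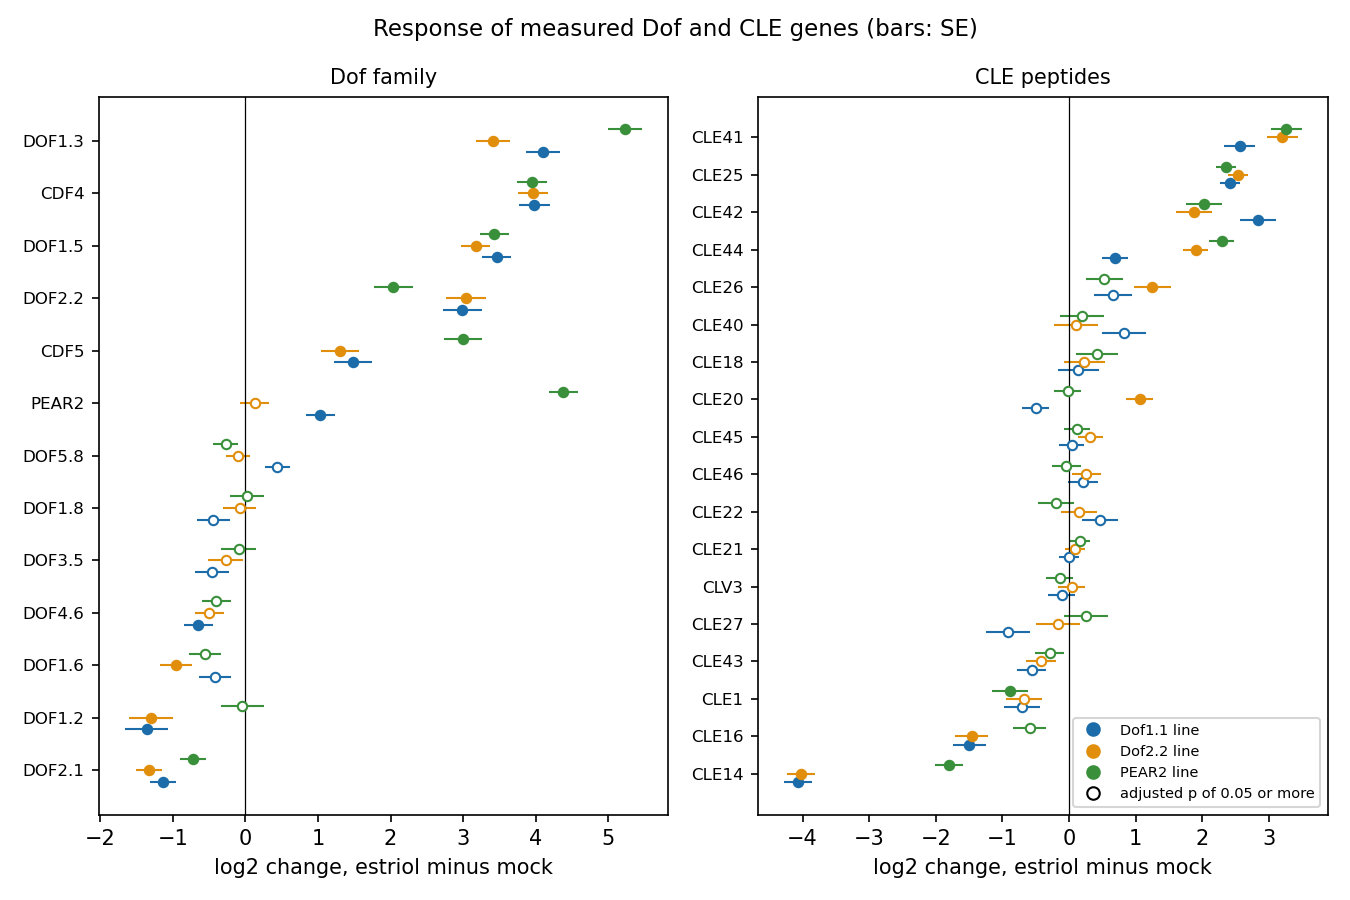
Log2 change from mock to estriol (horizontal axis) of the 13 measured Dof genes and 18 measured CLE genes, with bars for SE and filled points for an adjusted p under 0.05 in the line. CDF4 stood at 3.98, 3.96 and 3.95 and CLE14 at -4.07, -4.02 and -1.8.

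Genes of vascular and cambial signalling also changed. OPS, a polar protein of the protophloem, rose by 0.91, 1.29 and 1.21 (SE 0.15; adjusted p = 0.00103, 0.000118 and 0.000339) in the Dof1.1, Dof2.2 and PEAR2 lines. It was the 1 riser among 4 measured members of the list of CLE receptors and protophloem signalling, where 0 fell and 3 did not pass in each line, and adjusted over the list alone 1, 1 and 3 rose. That list gave adjusted p = 0.442, 0.668 and 0.227, and adjusted p = 0.747, 0.747 and 0.549 with an estimated correlation. PHV, an HD-ZIP III transcription factor, rose by 2.03, 1.24 and 0.99 (SE 0.16; adjusted p = 6.8e-06, 0.000227 and 0.00167). MOL1, a receptor kinase that represses cambium activity, rose by 1.75, 1.56 and 2.02 (SE 0.17; adjusted p = 3.09e-05, 8.32e-05 and 2.95e-05). These were the 2 measured members of the procambium list, and none of the lists of sieve element, xylem and jasmonate genes had a measured member. SWEET11, the 1 measured gene of the companion cell list, stood at 1.48 ± 0.55 (adjusted p = 0.064) in the Dof1.1 line and 0.29 (0.752) in the Dof2.2 line. The mitotic kinase AUR1, the 1 measured gene of 21 on the cell division list, rose by 1.36, 1.03 and 0.76 (SE 0.15, adjusted p = 7.61e-05, 0.000636 and 0.00639).

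Some genes of the hormone, root hair and endodermis lists also changed. Measured were 2 of 14 genes of the root hair list and 1 of 12 of the endodermis list. GH3.3, an auxin-conjugating enzyme, changed by -3.35, -3.96 and -1.74 (SE 0.37; adjusted p = 5.6e-05, 2.14e-05 and 0.00774) in the Dof1.1, Dof2.2 and PEAR2 lines. GH3.5 fell in the Dof1.1 and Dof2.2 lines at -1.43 and -1.62 (SE 0.2; adjusted p = 0.000336 and 0.000174), with -0.07 in the PEAR2 line (0.877). LBD29, a lateral root transcription factor, changed by -1.44, -1.85 and -1.26 (SE 0.39; adjusted p = 0.0165, 0.0052 and 0.0489). Of 5 measured auxin genes of 22, 0 rose and 3, 3 and 2 fell, leaving 2, 2 and 3 that did not pass, and adjusted over the list alone 4, 3 and 2 fell. The auxin list gave adjusted p = 0.0177, 0.0177 and 0.328 downward, and adjusted p = 0.549, 0.549 and 0.747 with an estimated correlation. With paired arrays the first pair became 0.0489 and 0.0532, and without Dof1.1 mock array 2 the Dof1.1 line's became 0.0588. The type-A response regulator ARR16 fell in the Dof1.1 and Dof2.2 lines at -3.06 and -3.97 (SE 0.38; adjusted p = 0.00013 and 2.6e-05), with -1.09 in the PEAR2 line (0.0734). ARR16 with estriol in the Dof1.1 and Dof2.2 lines and GH3.3 with estriol in the Dof2.2 line were dim. The vascular bHLH gene LHW rose by 0.63, 0.8 and 0.57 (SE 0.16; adjusted p = 0.0126, 0.00408 and 0.034). Of 3 measured cytokinin genes of 24, 1, 1 and 1 rose, 1, 1 and 0 fell, and 1, 1 and 2 did not pass. Adjusted over the list alone, 1 rose and 1 fell in each line. The cytokinin list gave adjusted p = 0.747, 0.593 and 0.816, and adjusted p = 0.764, 0.747 and 0.824 with an estimated correlation. Its median of 0.02 in the Dof1.1 line had the opposite sign to its mean of -0.8 and its test. The root hair expansins EXPA18, at -3.98, -5.16 and -1.88 (SE 0.15; adjusted p = 9.97e-08, 4.84e-08 and 2.17e-05), and EXPA7, at -3.49, -4.38 and -1.94 (SE 0.19; adjusted p = 5.25e-07, 2e-07 and 5.71e-05), fell in every line. SGN3, a receptor of Casparian strip formation, changed by -2.36, -2.4 and -0.81 (SE 0.24; adjusted p = 3.03e-05, 3.4e-05 and 0.0392). Leaving out single arrays ended the call of LBD29 in the Dof1.1 line (estriol array 1, 0.0763; estriol array 2, 0.057; mock array 2, 0.129), of LHW there (estriol array 1, 0.0677; mock array 2, 0.0735) and of GH3.3 in the PEAR2 line (estriol array 2, 0.0539). Calls in the PEAR2 line missed without each of its 4 arrays for LHW (up to 0.16), SGN3 (up to 0.19) and LBD29 (up to 0.238), of which the latter pair also missed without some arrays of other lines. LBD29 in that line also missed after quantile normalization (0.0594) and over all entries (0.0508), and LHW in the Dof2.2 line on that line's arrays alone (0.0544).

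Transport and stress genes filled the remaining lists. Measured were only 2 of 20 genes of the glucosinolate list and 1 of 14 of the nitrate list, and these are the genes given here. The glucosinolate transporters GTR1, at -1.5, -0.99 and -0.59 (SE 0.14; adjusted p = 2.27e-05, 0.000513 and 0.0169), and GTR2, at -1.42, -1.34 and -0.64 (SE 0.16; adjusted p = 6.62e-05, 0.00012 and 0.0184), fell in the Dof1.1, Dof2.2 and PEAR2 lines. HHO2 of the nitrate list changed by -0.55, -0.89 and -0.52 (SE 0.15; adjusted p = 0.0172, 0.00131 and 0.0369). UGT73B5, a glycosyltransferase of the xenobiotic list, changed by -1.81, -0.83 and -1.04 (SE 0.19; adjusted p = 4.84e-05, 0.00886 and 0.00361). UGT73B4 fell in the Dof1.1 line at -0.84 ± 0.19 (adjusted p = 0.00549), with 0.17 (0.546) and -0.18 (0.608) elsewhere, and the glutathione transferase GSTU25 rose in the Dof2.2 line by 1.54 ± 0.19 (adjusted p = 0.000142), with 0.45 (0.0927) and 0.42 (0.166) elsewhere. Of these 3 measured xenobiotic genes of 16, 0, 1 and 0 rose, 2, 1 and 1 fell, and 1, 1 and 2 did not pass, and adjusted over the list alone 1, 1 and 0 rose and 2, 1 and 1 fell. The xenobiotic list gave adjusted p = 0.328, 0.808 and 0.61, and adjusted p = 0.674, 0.824 and 0.747 with an estimated correlation. Lists with 1 measured gene included heat shock (BIP1 at -0.35, -0.52 and -0.53), hypoxia (HRA1 at 0.3, -0.14 and 0.45), photosynthesis (RCA at -0.16, -0.4 and -0.52) and root cap (PLT4 at 0.25, 0.11 and 0.01). None of these 4 genes passed in any line (adjusted p from 0.0834 to 0.98), and BIP1 in the Dof1.1 and Dof2.2 lines and HRA1 in the Dof2.2 line were dim in both treatments. Single arrays decided the PEAR2 line's calls for GTR1 (any of its 4 arrays, up to 0.117), GTR2 (estriol array 1, 0.142; mock array 1, 0.0666; mock array 2, 0.12) and HHO2 (any of 6 arrays, up to 0.191). They also decided HHO2 in the Dof1.1 line (any of its 4 arrays, up to 0.0691; 0.0573 on that line alone) and UGT73B5 in the Dof2.2 line (estriol array 2, 0.0695), and paired arrays put HHO2 in the PEAR2 line at 0.0504.

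Much of the response was shared by the 3 lines. Among the 10 shared genes with the largest fitted mean change were AT1G47317 at 8.86, 8.71 and 8.46 and AT1G28630 at 8.25, 6.83 and 8.81 in the Dof1.1, Dof2.2 and PEAR2 lines. LCR29 followed at 8.48, 6.7 and 8.01, LCR42 at 8.26, 3.75 and 8.21, LCR30 at 7.43, 5.07 and 5.81, and LCR39 at 7.32, 4.62 and 6.32. The other genes of the 10 were AT5G59110 (7.01, 7.39 and 4.88), AT3G56520 (8.48, 4.48 and 6), AT1G16750 (6.59, 6.57 and 5.4) and AT1G59790 (6.85, 4.23 and 6.97). Except for AT1G47317 and LCR39, each was dim in mock roots of at least 1 line, so this rank is not exact. Genes past the threshold with one sign in all 3 lines numbered 2456, with 1002 higher (36.3 expected of independent lists) and 1454 lower (38.1 expected), of 6775 past it in at least 1 line. The model gave each gene 1 estimate of spread for all 3 tests. Genes of low spread can therefore pass together, and the expected counts are not a chance level. Without PEAR2 mock array 2 the 2456 became 1616, and without PEAR2 estriol array 1 they became 1630. The Dof1.1 and Dof2.2 lines shared 1777 higher and 1982 lower genes, the Dof1.1 and PEAR2 lines 1143 and 1557, and the Dof2.2 and PEAR2 lines 1106 and 1508. Genes past the threshold in opposite directions numbered 32, 10 and 5 for these pairs. The mean of the 3 inductions had 4330 genes higher and 3281 lower, 46% of those tested, of which 841 were higher and 1591 lower by at least 2-fold. Across genes, which are not independent replicates, changes correlated at Pearson's r of 0.86 (Dof1.1 and Dof2.2), 0.84 (Dof1.1 and PEAR2) and 0.85 (Dof2.2 and PEAR2), with Spearman's rho of 0.75, 0.71 and 0.73.

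**Figure D3:**
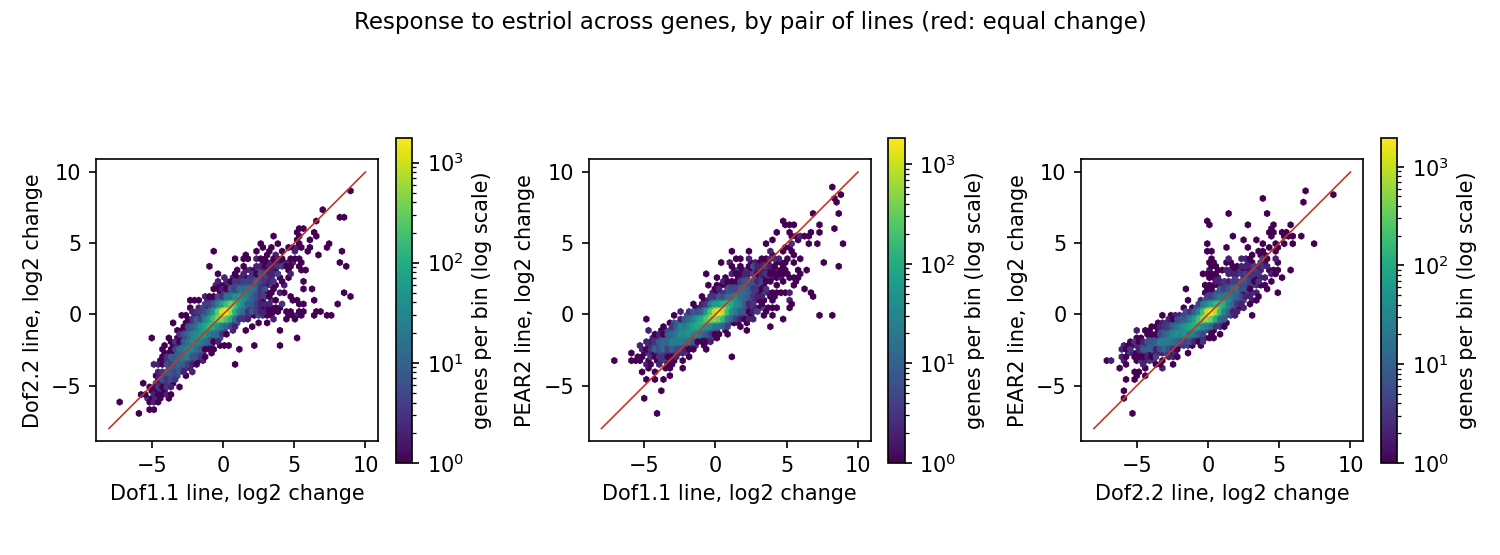
Log2 change from mock to estriol in one line (horizontal axis) against another (vertical axis) over 16548 genes, with colour for the number of genes per bin on a log scale and a red line for equal change. Pearson's r was 0.86, 0.84 and 0.85 from left to right.

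Some responses differed between lines, tested as the difference of the inductions. LCR16 went from 1.92 ± 0.07 to 9.49 ± 0.04 (SD, n = 2) in the Dof1.1 line and from 1.55 ± 0.16 to 1.57 ± 0.25 in the Dof2.2 line, a difference of 7.55 ± 0.23 (adjusted p = 2.7e-07), in which only the Dof1.1 estriol level was not dim. The germin-like gene AT5G38930 responded more in the Dof1.1 than in the PEAR2 line by 8.19 ± 0.41 (adjusted p = 3.14e-05; dim in all but the Dof1.1 estriol arrays), and the glycosyl hydrolase GH9A4 by 5.7 ± 0.32 (adjusted p = 3.71e-05). The root hair expansin EXPA18 fell further in the Dof2.2 than in the PEAR2 line, at -3.28 ± 0.22 (adjusted p = 9.58e-05). CLE14 fell further in the Dof1.1 than in the PEAR2 line (-2.27 ± 0.3, adjusted p = 0.00405), CLE44 rose less there (-1.6 ± 0.27, adjusted p = 0.0143), and CLE20 differed between the Dof1.1 and Dof2.2 lines by -1.55 ± 0.28 (adjusted p = 0.0228). Leaving out 1 array ended the difference of CLE44 for any of 3 arrays (up to 0.0686) and that of CLE20 for any of 6 (up to 0.094), and array weights put CLE20 at 0.0588. AT2G19802 was 1.04 in mock and 1 in estriol arrays of the Dof2.2 line and went from 1.12 to 7.57 in the PEAR2 line, a difference of -6.49 ± 0.28 (adjusted p = 1.02e-05), in which only the PEAR2 estriol level was not dim. In the counts that follow, higher and lower refer to the signed log2 change. A gene that fell further in the first line, as EXPA18 did in the Dof2.2 line, thus counts as lower. The Dof1.1 response was higher than the Dof2.2 response in 157 genes and lower in 97. Against the PEAR2 response it was higher in 205 and lower in 277, and the Dof2.2 response was higher than the PEAR2 response in 50 and lower in 225. These counts of 254, 482 and 275 moved with single arrays, as low as 148 without Dof1.1 estriol array 1, and 180 and 111 without PEAR2 mock array 1. The balance of 205 and 277 turned to 96 and 84 without PEAR2 mock array 1, 104 and 89 without mock array 2 and 128 and 120 without estriol array 1.

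Mock roots were compared between lines, where line and any batch are confounded, and background too except between the Dof2.2 and PEAR2 lines, which share it. The lines looked normalized separately, with median differences over all genes of 0.48 (Dof1.1 minus Dof2.2), -0.37 (Dof1.1 minus PEAR2) and -0.86 (Dof2.2 minus PEAR2), and values after quantile normalization are set beside these. The expansin-like gene EXLA3 was higher in the Dof1.1 than in the Dof2.2 line by 3.74 ± 0.46 (adjusted p = 0.0012; 3.13 after quantile normalization, 0.0147) and lower in the Dof2.2 than in the PEAR2 line at -4.52 ± 0.46 (adjusted p = 8.43e-05; -3.51 and 0.00627). The beta-glucosidase gene BGLU28 was higher in the Dof1.1 than in the Dof2.2 line by 3.57 ± 0.39 (adjusted p = 0.000937; 3.05 and 0.0112). The jacalin lectin gene JAL33 was lower in the Dof1.1 than in the PEAR2 line at -2.51 ± 0.29 (adjusted p = 0.00204; -2.23 and 0.0175), and the lectin gene AT3G16530 lower in the Dof2.2 than in the PEAR2 line at -3.9 ± 0.26 (adjusted p = 3.92e-05; -2.9 and 0.00124). EXLA3 and AT3G16530 were dim in mock roots of the Dof2.2 line, at 2.88 and 1.98. As normalized by the authors, 7227 genes were higher and 85 lower in the Dof1.1 than in the Dof2.2 line, 138 and 4618 in the Dof1.1 than in the PEAR2 line, and 30 and 13222 in the Dof2.2 than in the PEAR2 line. After quantile normalization the counts were 331 and 282, 195 and 224, and 483 and 560.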

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

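Among the tests of explanations below, the count over other splits of the arrays and the test of a transgene active without estriol were written before their results were seen, and the other tests were chosen only after, while the differences between lines themselves were planned.

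The response to induction differed between lines by a test of the difference in 254 genes (Dof1.1 against Dof2.2), 482 (Dof1.1 against PEAR2) and 275 (Dof2.2 against PEAR2). The 254 became 164 without Dof1.1 mock array 1, 169 without mock array 2, 148 without estriol array 1 and 167 without Dof2.2 mock array 1. The 482 became 255, 270, 299 and 293 without Dof1.1 mock arrays 1 and 2 and estriol arrays 1 and 2, and 180, 193, 248 and 202 without those of PEAR2. The 275 became 111, 144, 151 and 126 without the PEAR2 arrays in that order. Values below are differences of log2 changes, the first line minus the second, each past the adjusted threshold. In 48 of the 105 differences given, at least 1 group mean lay below the lower quartile of the table's entries and is not shown to lie above background, so their sizes and order are not exact.

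Comparing the Dof1.1 with the Dof2.2 response gave positive differences of 7.65 for AT1G18130, 7.55 for AT5G38930, 7.55 for LCR16, 7.39 for AT5G37940, 7.12 for AT3G42830, 6.69 for GH9A4, 6.5 for AGL90, 6.33 for AT1G35350, 6.31 for LCR40, 5.5 for AT4G12950, 5.14 for AT3G30280, 4.85 for AT2G19802, 4.5 for LCR42, 4 for AT3G56520, 2.69 for LCR39, 2.62 for AT1G59790, 2.35 for LCR30, 2.12 for AT4G22460, 1.87 for AT3G01190, 1.42 for AT1G28630, 1.26 for AT1G19900 and 1.18 for EXPA18. Negative differences were -5.18 for AT2G04070, -4.34 for AT1G36622, -3.19 for AT5G19880, -3.15 for AT1G59865, -3.13 for AT1G55450 and -1.55 for CLE20. Leaving out 1 array ended the call of LCR39 (6 arrays, up to 0.107), LCR30 (4 arrays, up to 0.066), AT4G22460 (1 array, 0.0541), CLE20 (6 arrays, up to 0.094), AT1G28630 (6 arrays, up to 0.09), AT1G19900 (7 arrays, up to 0.0834) and EXPA18 (10 arrays, up to 0.0929), with the number of arrays that do so and the highest adjusted p. Paired arrays ended those of AT2G04070 (0.0501), AT1G59865 (0.053), LCR39 (0.0622), AT1G28630 (0.0578) and EXPA18 (0.0757). Quantile normalization ended those of EXPA18 (0.0642), and array weights those of AT1G19900 (0.0666) and CLE20 (0.0588). On the arrays of these lines alone, calls were lost for LCR39 (0.0752), LCR30 (0.0635), AT4G22460 (0.0525), AT1G28630 (0.0816) and EXPA18 (0.107).

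Between the Dof1.1 and PEAR2 responses the positive differences were 8.19 for AT5G38930, 7.38 for AT5G37940, 5.7 for GH9A4, 5.32 for AT4G12950, 5.02 for LCR40, 4.15 for AT1G18130, 4.15 for AT1G35350, 3.96 for LCR16, 3.27 for AT5G40000, 3.17 for AT4G31660, 2.48 for AT3G56520, 2.46 for AT1G74130, 1.7 for AT4G22460 and 1.04 for PHV. On the negative side stood -4.05 for AT5G36130, -3.51 for AT2G04070, -3.46 for AT2G36690, -3.35 for PEAR2, -3.27 for AT2G18980, -3.16 for AT1G51840, -2.91 for GH9C1, -2.67 for AT1G51830, -2.65 for AT1G05660, -2.6 for AT1G51850, -2.59 for AT1G56630, -2.37 for AT3G45710, -2.27 for CLE14, -2.14 for AT1G14220, -2.1 for EXPA18, -1.64 for AT2G19802, -1.6 for CLE44, -1.56 for SGN3, -1.55 for AT3G01190, -1.55 for EXPA7, -1.36 for GH3.5, -1.32 for AT1G55450 and -0.91 for GTR1. Calls ended by leaving out 1 array were those of AT1G35350 (3 arrays, up to 0.0641), AT5G36130 (10 arrays, up to 0.167), AT2G04070 (8 arrays, up to 0.118), AT1G05660 (10 arrays, up to 0.157), AT1G56630 (7 arrays, up to 0.153), AT3G56520 (6 arrays, up to 0.101), AT3G45710 (7 arrays, up to 0.113), AT1G14220 (7 arrays, up to 0.149), AT4G22460 (6 arrays, up to 0.115), AT2G19802 (3 arrays, up to 0.0641), CLE44 (3 arrays, up to 0.0686), SGN3 (7 arrays, up to 0.138), EXPA7 (3 arrays, up to 0.0636), GH3.5 (7 arrays, up to 0.147), AT1G55450 (7 arrays, up to 0.115), PHV (8 arrays, up to 0.155) and GTR1 (10 arrays, up to 0.155), with the number of arrays that do so and the highest adjusted p. Paired arrays ended those of AT5G36130 (0.056), AT2G04070 (0.0823), AT1G05660 (0.0632), AT3G56520 (0.0723), SGN3 (0.0571), GH3.5 (0.0691) and GTR1 (0.0516). Quantile normalization ended those of AT5G36130 (0.0505), AT2G04070 (0.0511), AT1G05660 (0.0719), AT1G56630 (0.0601), PHV (0.0511) and GTR1 (0.0533). On the arrays of these lines alone, calls were lost for GTR1 (0.0514). The block by replicate number ended those of AT5G36130 (0.0681), AT1G05660 (0.0626) and PHV (0.0539), and testing all entries that of AT5G36130 (0.0524).

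For the Dof2.2 against the PEAR2 response the positive differences were 3.31 for SRS3, 3.04 for AT5G61890, 2.6 for AT5G40000, 2.58 for AT1G74130, 2.58 for AT4G31660, 2.08 for AT5G19880 and 1.81 for AT1G55450. Values under 0 were -6.49 for AT2G19802, -6.02 for AT3G30280, -5.59 for AT3G42830, -5 for AGL90, -4.46 for LCR42, -4.25 for PEAR2, -3.8 for AT1G51840, -3.76 for AT1G05660, -3.76 for AT2G36690, -3.72 for SWEET11, -3.67 for AT2G44380, -3.67 for GH9C1, -3.64 for AT1G51830, -3.59 for LCR16, -3.59 for AT2G47280, -3.5 for AT1G18130, -3.47 for AT3G45710, -3.42 for AT3G01190, -3.29 for AT3G46700, -3.28 for EXPA18, -2.96 for AT2G18980, -2.92 for AT1G14220, -2.88 for ARR16, -2.74 for AT1G59790, -2.7 for AT1G51850, -2.44 for EXPA7, -2.39 for AT2G19050, -2.22 for CLE14, -1.98 for AT1G28630, -1.82 for DOF1.3, -1.59 for SGN3, -1.55 for GH3.5 and -1.25 for AT4G09780. Without 1 array the calls were lost of AT1G05660 (2 arrays, up to 0.0638), SWEET11 (10 arrays, up to 0.166), SRS3 (5 arrays, up to 0.111), AT5G61890 (7 arrays, up to 0.127), AT1G14220 (2 arrays, up to 0.0662), ARR16 (6 arrays, up to 0.11), AT5G40000 (9 arrays, up to 0.148), AT4G31660 (1 array, 0.0517), AT2G19050 (3 arrays, up to 0.0756), AT5G19880 (3 arrays, up to 0.0575), DOF1.3 (7 arrays, up to 0.123), SGN3 (9 arrays, up to 0.168), GH3.5 (7 arrays, up to 0.134) and AT4G09780 (7 arrays, up to 0.0992), with the number of arrays that do so and the highest adjusted p. Paired arrays ended those of AT2G44380 (0.0613), AT2G47280 (0.0514), SRS3 (0.117), ARR16 (0.0669), AT5G40000 (0.0656), AT2G19050 (0.0613), DOF1.3 (0.0833), SGN3 (0.078), GH3.5 (0.0738) and AT4G09780 (0.0605). Quantile normalization ended those of AT5G40000 (0.0866), SGN3 (0.0589) and GH3.5 (0.0505). On the arrays of these lines alone, calls were lost for AT1G05660 (0.0509), SWEET11 (0.139), SRS3 (0.0778), ARR16 (0.0613) and SGN3 (0.0762). The block by replicate number ended those of AT5G61890 (0.051) and SGN3 (0.0664), and testing all entries that of SWEET11 (0.0527).

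Entries of the table without exactly 1 gene name, not used in the comparisons, also responded. Of 11861, 4541 (38.3%) changed in the Dof1.1 line, 3953 (33.3%) in the Dof2.2 line and 2426 (20.5%) in the PEAR2 line.

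The mean induction over the lines had 7611 genes past the threshold. In 100 of the 108 splits of the arrays within lines, 1 split gave as many, the real one, and the highest of the other splits gave 3901. The other splits mix mock and estriol arrays of a line or exchange them, so a true response lowers their counts. The smallest share attainable is 1 in 100. The real split ranked first, and this does not exclude chance. The splits that part as many pairs as the real one numbered 30 among these, with 3667 as their highest other count.

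The first pattern weighed is the rise of 114 genes by at least 8-fold on average, of which 110 passed in all 3 lines and 6 belong to the LCR family. Their median levels went from 3.68, 3.08 and 4.02 in mock roots to 8.71, 7.24 and 8.42 with estriol in the Dof1.1, Dof2.2 and PEAR2 lines. After quantile normalization over all arrays 114 of these genes still rose 8-fold. That step starts from the authors' finished values and cannot undo their background correction. It does not decide whether their normalization made the rises. The tables argue against noise of dim signals. Genes chosen for such a rise on arrays of one replicate number (114 and 119 genes, 110 of the pattern each time) had a median change of at least 3.66 in arrays of the other. For 25 of the 114 genes of the pattern (21.9%, against 1.7% of all genes) the response differed between the Dof2.2 and PEAR2 lines, which share a background. Genes with large rises have more room to differ than all genes, so these shares are not alike. For those 25 the differences argue only against estriol acting alike in both lines as the whole cause. Line and any batch are confounded, so an estriol effect that differs between lines or batches stays open for them. For the other genes estriol itself and the Dof transgenes cannot be told apart, because 0 lines without a Dof transgene were treated.

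The second pattern is the smaller response of the PEAR2 line, with slopes over the 7611 genes, fitted by orthogonal regression through 0, of 0.68 on the Dof1.1 response and 0.74 on the Dof2.2 response, where the Dof2.2 response on the Dof1.1 response had 0.92. The PEAR2 line stood apart in the falls, with slopes of 0.63 on either response for genes lower in the mean, where Dof2.2 on Dof1.1 had 1, and not in the rises, with 0.94 on Dof2.2 and 0.74 on Dof1.1, where Dof2.2 on Dof1.1 had 0.78, and it had 42 falls and 117 rises of at least 8-fold against 350 and 114 in the Dof2.2 line and 314 and 180 in the Dof1.1 line. The slope on the Dof1.1 response was 0.67 in the brighter part of genes (0.66 to 0.69 leaving out each array). This part was chosen by mean signal over all arrays and can hold genes that fall to dim levels with estriol. Its slope therefore does not decide on compression by higher background signal. After quantile normalization over all arrays the slope was 0.69, which argues against a difference in signal scale between the lines. That step cannot undo the authors' background correction. A transgene active without estriol would make mock levels in the PEAR2 line follow the response of the remaining line, and the larger of those slopes was -0.006 (both slopes lay between -0.031 and 0.014 leaving out each array), which argues against it as the cause, although the PEAR2 transcript itself was higher in mock roots of its line after quantile normalization, at 7.43 against 6.08 (adjusted p = 0.022) and 6.34 (0.0222). Differences in activity between the Dof proteins and in transgene level remain open and were not tested. Background remains open against the Dof1.1 line only, since the Dof2.2 and PEAR2 lines share theirs. Any batch is confounded with line and cannot be told apart from these causes.

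The third pattern is the rise of DOF2.2 in the Dof1.1 line, as large as in its own. The rise in its own line also did not pass as different from that in the PEAR2 line (1, SE 0.39, adjusted p = 0.339). Saturation of the DOF2.2 probes stays open, because probes of other genes saturate at other signals. Neither the percentile of 88.8 (86.1 and 91.1 in single arrays) nor the gap of at least 4.04 to the brightest gene decides it. Exchanged labels of the Dof1.1 and Dof2.2 lines stay open, because the rises there differed by -0.05 (SE 0.39, adjusted p = 0.992) and the Dof1.1 transcript is not followed. Probes reading other Dof transcripts also stay open, since DOF2.2 rose by 2.04 in the PEAR2 line. A rise of the native DOF2.2 gene after induction of another Dof gene is a further possibility that was not tested.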

How the results depend on the processing

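The alternative without the transgenes was chosen after seeing the data, and the others were planned. Of 6574 values of named genes recomputed under 21 alternatives, 6160 kept direction and side of the threshold, 399 lost it (54 genes), 15 gained it and 0 reversed. Without the dimmest genes the correlations of responses became 0.884 (Dof1.1 and Dof2.2), 0.872 (Dof1.1 and PEAR2) and 0.873 (Dof2.2 and PEAR2), over fewer genes. Genes that differed between mock groups fell to 613, 419 and 1043 after quantile normalization and 630, 715 and 1681 with arrays centred on the 75th percentile, which remove the shift between lines. On the arrays of the lines compared alone, 3095 genes changed in the Dof2.2 induction and 154 in Dof1.1 against Dof2.2, while the PEAR2 induction had 3471 in place of 3105 and Dof1.1 against PEAR2 677 in place of 482. That setting put 2 list tests of 18 past the threshold in place of 3, and the cause was not tested. List tests past it numbered 1 with same-numbered arrays as pairs, 0 with camera and an estimated correlation (1 before adjustment), 12 with fry, which asks another question, and 2 without DOF2.2 and PEAR2 in the Dof list. Over all entries, more were tested, with 10324, 8829 and 5621 changed in the inductions, 13890 in their mean, 397, 854 and 490 in the differences, 13184, 8736 and 23291 between mock groups and 4516 shared by the lines. A 2-fold minimum, stricter by construction, left 3056, 2525 and 1778 in the inductions, 2432 in their mean, 1629, 1141 and 6116 between mock groups and 1427 shared. Leaving out single arrays, where the lone array is assumed to vary like other groups, gave 4358 to 5668, 3441 to 4792 and 1859 to 3184 in the inductions and 6742 to 7425 in their mean. It gave 148 to 277, 180 to 640 and 111 to 355 in the differences, and 4387 to 7282, 1260 to 4766 and 11107 to 13337 between mock groups. Shared genes ranged from 1616 to 2308, correlations from 0.825 to 0.862, 0.823 to 0.842 and 0.821 to 0.846, and list tests past the threshold from 2 to 3. The mock counts 7312 and 4756 also moved with single arrays. The first became 4772 and 4813 without Dof1.1 mock arrays 1 and 2, and 4742 and 4387 without those of Dof2.2, and the second 2705, 2662, 1260 and 1626 without the mock arrays of Dof1.1 and PEAR2. Paired arrays as a block gave 6525, 5601 and 3663 genes in the inductions, of which 5440, 4544 and 2927 are among those without the block. The block changed no call of a named gene or of a list fixed before the data were examined beyond those given with their values, and gives no value between mock groups. Trended robust moderation, array weights and the block by replicate number kept each total within 1.5 times. By direction, array weights took the rises in the PEAR2 induction from 1378 to 2120, the lower genes in Dof1.1 against Dof2.2 from 97 to 59 and those between their mock groups from 85 to 45. Only the arrays of the lines compared gives no separate value for the mean induction. The majority of 2940 higher against 2683 lower in the Dof1.1 induction turned with centring (2607 and 2802), array weights (2460 and 2475), on that line's arrays alone (1997 and 2362) and without its mock array 1 (2150 and 2336), estriol array 1 (2198 and 2234) or estriol array 2 (2094 and 2264). That of 2452 against 2252 in the Dof2.2 induction turned with centring (2184 and 2338), on that line's arrays alone (1392 and 1703) and without its mock array 1 (1851 and 1994), mock array 2 (1646 and 1928), estriol array 1 (1918 and 1985) or estriol array 2 (1667 and 1774). A 2-fold minimum turned both (1152 and 1904, 929 and 1596) and that of the mean induction, from 4330 and 3281 to 841 and 1591. The median change of all genes stayed between 0.07 and 0.13 in the Dof1.1 and Dof2.2 inductions under these alternatives. What signal over background limits was not tested beyond the dim genes left out.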

Other observations

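The tests below used lists chosen after the gene names were known and before expression was compared, except that an F-box gene with the symbol LCR was taken out of the LCR family, and these lists were run under the alternatives, only after their results were seen.

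Of 87 tests of 29 added lists, 14 passed with the preset correlation of camera and 0 with an estimated correlation (8 before adjustment), and fry gave 55. Class III peroxidases, 62 measured, had 10 that rose and 31 that fell in the Dof1.1 line, 13 and 34 in the Dof2.2 line and 9 and 25 in the PEAR2 line. Their median changes were -0.74, -0.75 and -0.59, with adjusted p = 1.39e-05, 1.68e-05 and 0.000138, and 0.122 in each line with an estimated correlation. The root hair genes EXPA18 (-3.98, -5.16 and -1.88) and EXPA7 (-3.49, -4.38 and -1.94) and the endodermis gene SGN3 (-2.36, -2.4 and -0.81) also fell in every line. They were the only measured genes of lists of 14 and 12, too few to tell of a cell type. Among the peroxidases AT4G30170 changed by -4.58, -5.82 (to 2.69, below the lower quartile of entries) and -2.84 and AT1G71695 by 3.9, 3.5 and 3.46. UDP-glycosyltransferases, 51 measured, had 1 riser and 25 fallers, 3 and 19, and 1 and 18, with adjusted p = 1.2e-05, 0.000102 and 0.000138, and 0.122 with an estimated correlation. UGT72E1 changed by -3.98, -5.24 and -1.98, and UGT74F1 by 2.29, 2.75 and 2.54. The TBL family, 23 measured, had 2 and 10, 2 and 12, and 1 and 8, with adjusted p = 0.00528, 0.000798 and 0.00309, and 0.435, 0.415 and 0.435 with an estimated correlation. The SCPL family, 32 measured, passed downward in the Dof2.2 line, where 1 rose and 10 fell, with adjusted p = 0.0477, and 0.647 with an estimated correlation. It also passed in the PEAR2 line, where 1 rose and 6 fell (0.033 and 0.602). In the Dof1.1 line 2 rose and 11 fell (0.0798 and 0.708). The family passed there without the dimmest genes (0.0113), a filter by mean signal over all arrays that can favour genes that changed. Cytosolic ribosomal protein genes, 107 measured, passed upward in the Dof1.1 line (9 rose and 0 fell; 0.00805 and 0.824) and the Dof2.2 line (8 and 0; 0.00652 and 0.824), with a median change of 0.25 in each. Risers were a smaller share of these ribosomal genes than of all 16548 genes, of which 2940 rose in the Dof1.1 line and 2452 in the Dof2.2 line. The median change of all genes was 0.11 and 0.1 there. The 4 genes named from the lists of this paragraph were picked after their values were seen. With paired arrays 12 of the 14 calls held, and ribosomal proteins in the PEAR2 line passed (0.0442). The ribosomal call in the Dof1.1 line was lost without mock array 1 (0.589) or estriol array 2 (0.451) of that line, and that in the Dof2.2 line without its mock array 2 (0.0505). The SCPL call in the Dof2.2 line was lost with paired arrays (0.0532), with centring (0.0572), with the block by replicate number (0.0513) and without any of 6 arrays (up to 0.143), and that in the PEAR2 line without its estriol array 1 (0.129). Calls of peroxidases, UDP-glycosyltransferases and the TBL family held, at the preset correlation, under all 20 alternatives run for these lists.

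The LCR family, 63 measured, had 13 that rose and 0 that fell in the Dof1.1 line, 9 and 1 in the Dof2.2 line, and 10 and 0 in the PEAR2 line. Of all 16548 genes, 2940, 2452 and 1378 rose and 2683, 2252 and 1727 fell. The share of risers in the family was thus near that of all genes in the Dof1.1 and Dof2.2 lines. The family's test gave adjusted p = 0.0703, 0.345 and 0.0187, and 0.528, 0.73 and 0.435 with an estimated correlation. With the F-box gene, 64 genes, it gave 0.0497, 0.275 and 0.0124, so the call in the Dof1.1 line rested on that gene. The call in the PEAR2 line was lost after quantile normalization (0.0673), with paired arrays (0.0559) and without PEAR2 estriol array 1 (0.065). The Dof1.1 line passed on its arrays alone (0.0378). It also passed without the dimmest genes (0.00022), as did the Dof2.2 line (0.0242). That filter used mean signal over all arrays, estriol arrays included. It can keep dim members that rose and leave out dim members that did not, so these lower values do not tell of the family.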
